A study of Mus musculus with 4 samples.

How the data were processed

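RNA of E14 ES cells, iPS lines 7 and 13 and BMMNCs was labelled with Cy3 and hybridised to single-colour Agilent mouse arrays, per the labels' protocols. The slide was read with Agilent Feature Extraction 9.5, per the labels (9.5.1.1 per the file headers), and all 4 arrays lie on 1 slide with 1 scan time, per the file headers, so slide and scan cannot differ between groups. The deposited values are intensities: a processed signal per spot, background-subtracted and spatially detrended within the array, per the file headers. Spots near background carry a small positive surrogate value there, so such a probe has a bound in place of a level. No spot was saturated. The authors also deposited an intensity table, which was found to be the processed signal divided by 1 factor per array, on a linear scale and not centred by gene; the columns have medians of 139.9 (ES cells), 135.9 (line 7), 133.6 (line 13) and 106.2 (BMMNCs), and how the factors were set stays unknown.

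Control spots and 14 probes with outlier spots on an array were left out, spots of a probe were averaged, and the log2 processed signal minus the array's 75th percentile was used. A probe counted as well above background on an array when at least a share of 0.5 of its spots carried that mark. The files name probes by accession and hold no gene names. Accessions, without versions, were matched to the RefSeq gene table of assembly GRCm38.p6, which named 22951 of 41174 probes; others kept the file's name as a transcript. The arrays were designed on an older build, so the table served for names, chromosomes and gene order, and no coordinates are given. A gene with several probes took the probe with the highest mean signal, and 33378 genes or transcripts resulted, 16356 with a symbol. The 21216 above background on at least 1 array were tested, 13033 of them with a symbol.

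limma 3.58.1 in R 4.3.3 was fitted over all arrays with a mean for ES cells, iPS lines and BMMNCs and 1 residual degree of freedom from the 2 lines; the prior had 1.81 degrees of freedom and an SD of 0.094. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The single ES and BMMNC arrays are thereby taken to vary like the lines, which no array here can check. ES cells against BMMNCs and line 7 against line 13 compare single arrays and were described by size rules alone; for the former the fit could have given a test, which was not run. The size rules were: at least 4-fold against BMMNCs, at least 2-fold elsewhere, in both lines where both enter, with the higher side well above background. On simulated data with 21216 genes, 50 changed at each fold, iPS against ES recovered 0% at 2-fold and 4-fold, 66% at 8-fold and 82% at 16-fold with 3 false calls. iPS against BMMNCs recovered 0%, 2%, 70% and 88%, with 6 false calls. In the data far more genes differed, 6412 by at least 4-fold from BMMNCs and 1381 by at least 2-fold from ES cells, in both lines. The adjusted threshold was looser there, with calls down to log2 differences of 0.34 and 0.99, so the recovery figures do not carry over. All simulated arrays had the spread of the lines, so the false calls do not test that assumption.

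Where a gene was not well above background in a whole group, "at least N-fold" compares the bright group's mean with, per array of the dim group, the higher of the gene's own signal and the lowest signal of any probe well above background. Probes with 10 spots had a spot SD of 0.081 to 0.096 on the log2 scale. Before the data were examined, 28 gene lists with 420 members were fixed; 385 had a matched probe and 366 were tested. Nanog, Fgf4 and Nodal are among the genes with no probe matched by name and are not analysed here. Besides counts past the threshold over all genes and over the list alone, a list's median was placed among medians of 10000 random lists matched on mean expression in 20 bins, as a description of these arrays.

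Named genes followed a rule fixed before the data were examined: from each list the first 2 members on the array and the member with the largest difference measured on both sides, all reprogramming factors, and the 5 highest and 5 lowest genes with a symbol, measured on every array compared and past the threshold. In iPS against ES and between lines, list members were named where past the threshold or 2-fold apart. Not every gene that the rule gives is named in the text. Other genes in the text complete counts of 5 or fewer or belong to the chromosome tests, and were chosen after their values were seen. Some tests were revised after values were seen: the macrophage test first used the median of the whole list, 0.008, the strain test first excluded strain where its share lay at or below the median of random lists, a rule that its value met before it was replaced, and its genes were limited to those above background on all arrays. For blood lists as a whole, a median and a share of genes 2-fold higher in iPS than in ES cells were both computed, and neither is weighed here. Probes of a named gene disagreed in sign for Myc, Gata6, Tcstv1 and Pax6 against BMMNCs, for Myc against ES cells, and for Vav1, Cacna1a, Rassf4 and Sh2d1b1 between lines.

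Other settings tried were normexp background correction with an offset of 50, quantile normalization, median scaling, the authors' table, no filter on dim probes, a filter on all arrays, a floor, the mean of a gene's probes, single probes, limma with a trend or robust prior, an added 2-fold rule, ES and iPS arrays as 1 group, and leaving out either line. The files hold no mean signal, so normexp used the median signal and its local background. Runs without chromosome 8 or without fibroblast and macrophage genes were added after the data were seen. A slide block was not run because there is 1 slide. Figures were drawn with matplotlib 3.10.9.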

Results

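Gene expression was measured in 4 RNA samples of the mouse: E14 embryonic stem (ES) cells, a widely used line of strain 129 (n = 1); induced pluripotent stem (iPS) lines 7 and 13, made from bone marrow mononuclear cells (n = 2); and bone marrow mononuclear cells themselves (BMMNCs, n = 1), the white and nucleated red cell precursors of marrow. The iPS lines and BMMNCs were labelled C57BL/6, and the iPS lines came from mice with an EGFP reporter of Oct4. ES and iPS cells grew on irradiated embryonic fibroblasts, the feeder cells, which were depleted on gelatin before RNA was taken. Each sample was read on a single-colour Agilent array with 41174 distinct probes, of which 57.4% (ES cells), 59.0% (line 7), 56.1% (line 13) and 54.6% (BMMNCs) were well above background. The 75th percentile of signal was 1048, 1120, 1123 and 602, and the number of arrays limits the precision of every comparison. All levels below are log2 signals relative to that percentile, and 21216 genes or transcripts entered the comparisons.

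The series title speaks of reprogramming adult marrow cells, so the iPS lines were first set against the BMMNCs. Genes of pluripotency stood far higher in both iPS lines. Pou5f1 and Sox2, transcription factors of the pluripotent state, were at 4.73 and 3.89 in line 7 and at 4.74 and 3.9997 in line 13, and neither was well above background in BMMNCs. They were at least 784-fold and at least 453.5-fold higher in the iPS lines (limma adjusted p = 0.000703 for each). Klf4 rose by 1.09 on the log2 scale (SE 0.13, 2.12-fold, adjusted p = 0.00897), and Myc fell by 1.23 (SE 0.13, 2.34-fold, adjusted p = 0.00658). These 4 genes were named as the reprogramming factors list, whose tally was 3 risen and 1 fallen. The other probes of Myc gave differences of -0.75 and 0.08.

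Of 26 pluripotency genes tested, 25 rose and 1, Klf2, fell (log2 difference -1.06), with the same tally adjusted over the list alone. Zfp42, a zinc finger gene of ES cells, was at least 332.8-fold higher, and Esrrb, an orphan nuclear receptor, at least 329.9-fold higher. Dppa5a, an RNA-binding protein of early embryos, had the largest rise among genes above background on every array, 11.96 (SE 0.092). Tdh, which breaks down threonine in mouse ES cells, followed with 11.19 (SE 0.12). Col18a1, Igfbp2 and Col1a2 completed the 5 highest, with rises of 9.44, 9.37 and 9.26.

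Blood cell genes stood far lower in both iPS lines. All 17 pan-haematopoietic genes fell, among them the leukocyte phosphatase Ptprc (log2 difference -8.32, SE 0.11) and the small GTPase Rac2 (-8.38, SE 0.13), while the myeloid factor Spi1 was at least 14.1-fold lower. In the granulocyte list 20 of 20 fell: Mpo, myeloperoxidase, was at least 11040-fold lower, Elane at least 281.3-fold lower, and Chil3 fell by 12.98 (SE 0.11). All 16 erythroid genes fell, with the globin gene Hba-a1 at least 29000-fold lower and Slc4a1, the anion exchanger of red cells, which fell by 11.21 (SE 0.098). In the B cell list 15 of 15 fell, including Dntt (-8.42, SE 0.14), while Cd79a was at least 15.1-fold lower. Of 17 T and NK cell genes 15 fell, among them Ccl5 (-5.11, SE 0.20) and Cd3g (at least 34.5-fold lower). Tcf7 rose, and Cd3e was at -2.23 in line 7, -3.47 in line 13 and -2.50 in BMMNCs (adjusted p = 0.65).

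All 10 megakaryocyte genes fell, with Itga2b at -3.90 (SE 0.21), Pf4 at -2.32 (SE 0.15) and Ppbp at -3.77 (SE 0.27). All 12 monocyte and macrophage genes fell, but by unequal amounts: Cybb by 9.14 (SE 0.093), Cd14 by 1.84 (SE 0.13) and Fcgr1 by 1.76 (SE 0.12). Of 12 haematopoietic progenitor genes 10 fell, including Cd34 (-5.30, SE 0.11) and Flt3 (at least 12.8-fold lower), and Procr rose. Among genes with a symbol above background on the iPS and BMMNC arrays, Hbb-bt, Hdc and Lyl1 joined Chil3 and Slc4a1 as the 5 lowest. Their differences were -12.48, -9.74 and -9.34. Antigen presentation genes also fell in 12 of 12 cases, led by the class II gene H2-Ab1 (-8.20, SE 0.14), with H2-D1 at -3.75 and B2m at -1.32.

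**Figure D1:**
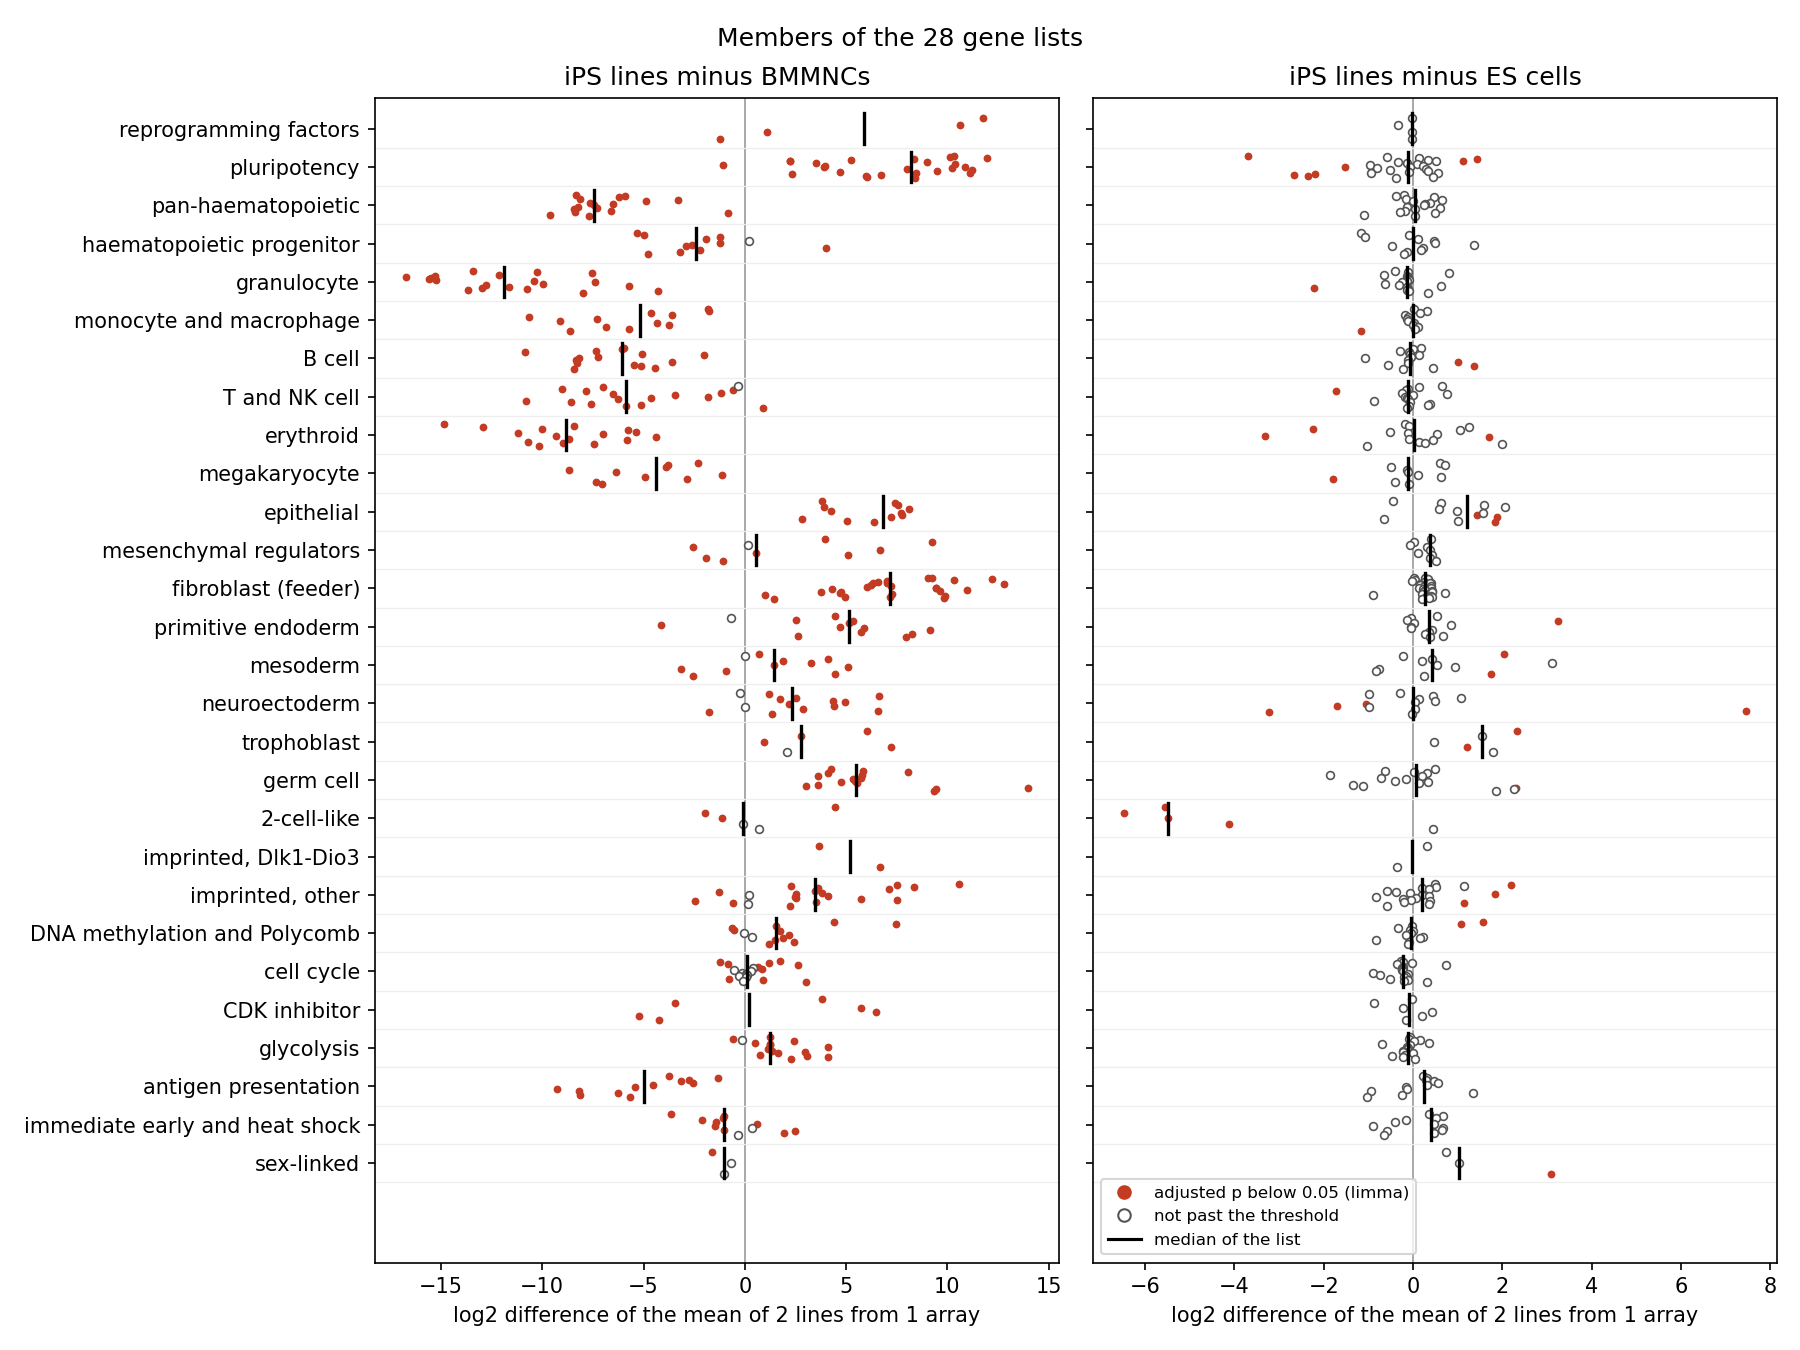
Each point is a tested member of 1 of the 28 gene lists, placed at its log2 difference of the mean of the 2 iPS lines from the BMMNC array (left) or the ES array (right); filled points passed limma's adjusted p of 0.05, open points did not, and bars mark list medians. Differences of genes not well above background on a side are shown as measured, not as bounds; the granulocyte median lies at -11.89 on the left and -0.13 on the right, and the 2-cell-like median at -5.48 on the right.

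All 12 epithelial genes rose, with the E-cadherin gene Cdh1 at 3.82 (SE 0.10), the keratin gene Krt8 at 7.54 (SE 0.61) and Epcam at least 171.6-fold higher. All 27 fibroblast (feeder) genes rose too: the collagen genes Col1a1 and Col1a2 rose by 9.03 (SE 0.095) and 9.26 (SE 0.10), and stood at 6.85 and 7.30 in ES cells. Mesenchymal regulators were mixed, with 5 risen and 3 fallen of 9. Snai2 was at least 128.4-fold higher and Snai1 rose by 3.95 (SE 0.10). The arrays do not show which cells of the iPS cultures, stem cells or remaining feeders, gave these rises or those of the lists below. In the primitive endoderm list 11 rose and 1 fell of 13, including the matrix gene Sparc (7.95, SE 0.096) and Gata6 (at least 15.7-fold higher). Gata4 was not well above background on either iPS array and at -4.41 in BMMNCs. Another probe of Gata6, below background on every array, gave -0.11.

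All 16 germ cell genes rose, among them Ddx4 (4.28, SE 0.18), Stra8 (5.71, SE 0.24) and Dazl (at least 13.2-fold higher). The mesoderm list gave 7 risen and 3 fallen of 11, with Eomes up by 0.72 (SE 0.095; 0.041 and adjusted p = 0.974 with ES and iPS arrays as 1 group) and Tbx6 down by 3.14 (SE 0.10). T, its first gene, was not well above background on any array. In the neuroectoderm list 11 rose and 1 fell of 14. Nes rose by 6.61 (SE 0.17) and Pax6 by 1.19 (SE 0.095). The other probe of Pax6, below background on every array, gave -0.30. Under 11 other settings Pax6 ranged from 0.44 to 1.51 and passed in 9. Sox1, above background in ES cells and line 7 alone, differed by -0.23 and did not pass (limma adjusted p = 0.115). Of 5 trophoblast genes 4 rose: Cdx2 was at least 13.7-fold higher, Elf5 at least 1.97-fold higher, and Ascl2 rose by 0.97 (SE 0.13); with normexp Elf5 and Ascl2 differed by 0.073 and 0.16 and did not pass. Of 5 2-cell-like genes 1 rose and 2 fell: Zscan4c was at least 15.6-fold higher, and Tcstv1 fell by 1.98 (SE 0.46), although its probes differed in sign. Tcstv1 turned to 0.021 with the mean of its probes and to 0.18 with ES and iPS arrays as 1 group. Zscan4c went down to 2.24 on the log2 scale and did not pass in every setting.

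Imprinted genes were mostly higher: 16 rose and 3 fell of 21 outside the Dlk1-Dio3 region, with Igf2 at least 453.2-fold higher, Peg3 at least 37.6-fold higher and Mest up by 7.11 (SE 0.098). The fibroblast list, with a median of 7.15, was higher in the same comparison, and Igf2 was 0.21 higher in line 7 than in line 13, where fibroblast genes had a median of 0.14. Within the Dlk1-Dio3 region Dlk1 and Dio3, the 2 tested, were at least 11.4-fold and at least 29.3-fold higher. The de novo methylation genes Dnmt3l and Dnmt3b rose by 7.46 (SE 0.092) and 4.42 (SE 0.094), in a list with 9 risen and 2 fallen of 13. Glycolysis genes rose in 15 of 17 cases, with Aldoc at 4.12 (SE 0.15) and Hk2 at 1.25 (SE 0.12), while Hk1 fell by 0.58 (SE 0.094). Cell cycle genes gave 7 risen, 3 fallen and 9 not past the threshold, from Mybl2 (3.01, SE 0.097) and Ccnb1 (1.73, SE 0.11) to Ccna2 (-1.24, SE 0.11). The list's median of 0.12 lay at percentile 46.1 of random lists.

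Among the CDK inhibitors Cdkn1a rose by 3.81 (SE 0.14), Cdkn2c fell by 5.22 (SE 0.093) and Cdkn1b was at least 9.45-fold lower, with 3 risen and 3 fallen of 6. Of 12 immediate early and heat shock genes 3 rose and 7 fell, Fos by 3.65 (SE 0.13) and Fosb by 1.01 (SE 0.10). Of the sex-linked genes, Ddx3y fell by 1.61 (SE 0.22), the other 2 tested did not pass, and Xist was not well above background on any array. Adjusted over the list alone, tallies changed in 2 lists: 4 immediate early and heat shock genes rose, and all 3 sex-linked genes fell.

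Over all genes, 8121 rose and 7927 fell, 75.6% of those tested, at limma's adjusted p of 0.05. This split depended on scaling, with 7464 risen and 10028 fallen under normexp, 7095 and 9072 under median scaling, and 8690 and 7383 with the authors' table. In both lines at least 4-fold apart were 3250 higher and 3162 lower genes, 3513 of these 6412 above background on a single side. Lower genes were the more numerous with quantile normalization (3185 higher and 3235 lower), median scaling (2970 and 3499), normexp (1618 and 2031) and above background on all arrays (1222 and 1458). The fit has 1 residual degree of freedom, from lines 7 and 13, and takes the ES and BMMNC arrays to vary as the lines do. Separate cultures or animals are not stated beyond the line numbers, so p-values measure the spread between these samples, which may be partly technical.

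**Figure D2:**
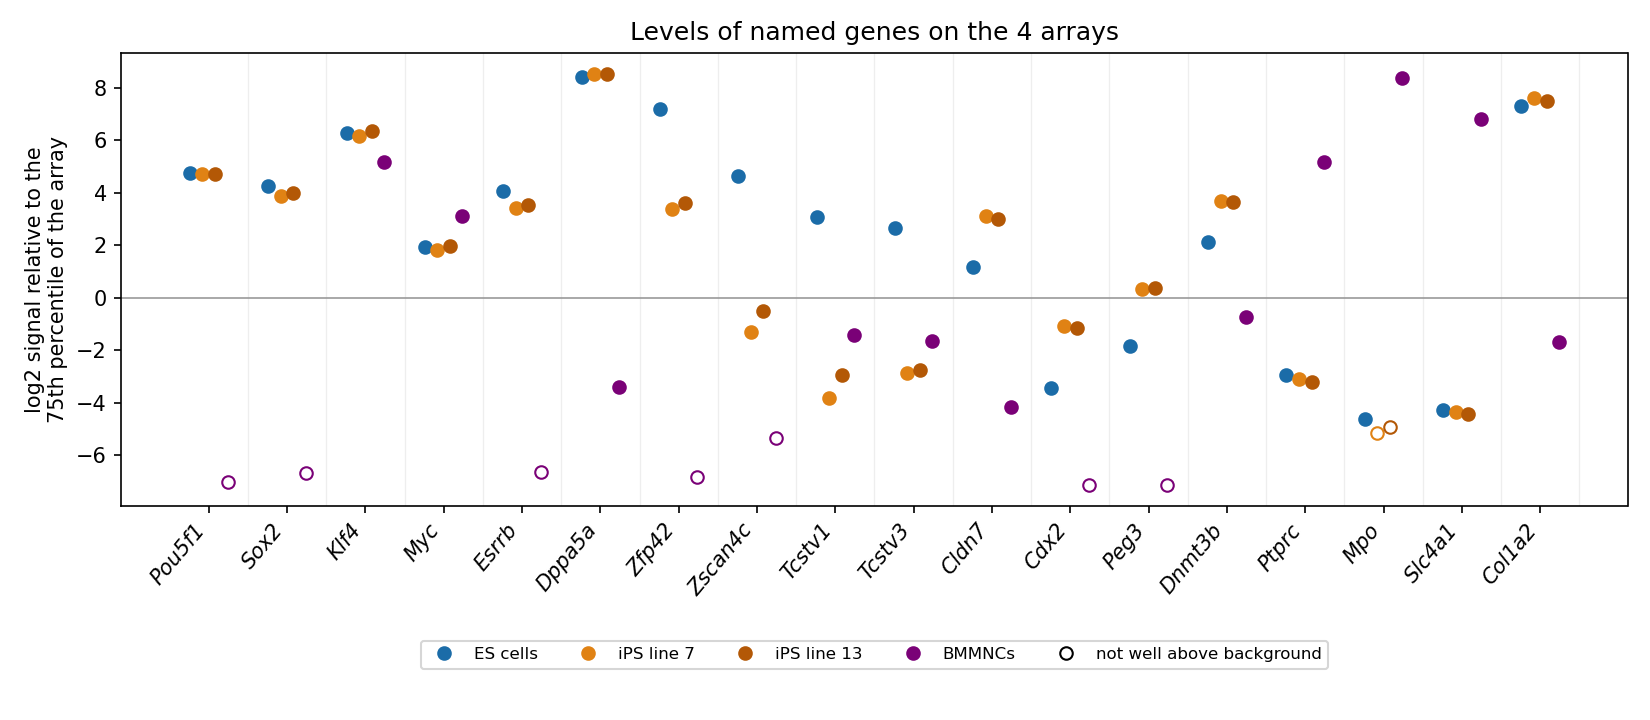
Log2 signal relative to the array's 75th percentile (vertical axis) for 18 genes on the ES, iPS line 7, iPS line 13 and BMMNC arrays, 1 point per array; open points were not well above background. Pou5f1 lies between 4.73 and 4.76 on the ES and iPS arrays, while Zfp42 is at 7.19 in ES cells and at 3.37 and 3.62 in the iPS lines.

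The iPS lines were then compared with ES cells, the reference for the pluripotent state. The reprogramming factors did not pass the test in the chosen setting: Pou5f1 differed by -0.02 (SE 0.092, adjusted p = 0.885), Sox2 by -0.33 (SE 0.11; adjusted p = 0.00843 with an intensity trend, past the threshold), Klf4 by -0.01 (SE 0.13) and Myc by -0.02 (SE 0.13), and the signs for Pou5f1, Klf4 and Myc changed with the scaling. Genes of the 2-cell-like state, which a small share of ES cells enter at any time, stood far lower in both lines, and 4 of 5 fell. Tcstv1 fell by 6.48 (SE 0.46, 89.1-fold, adjusted p = 0.0451), Zscan4c by 5.56 (SE 0.42, 47.0-fold, adjusted p = 0.0456) and Tcstv3 by 5.48 (SE 0.12, 44.5-fold, adjusted p = 0.0425). The list's median of -5.48 lay below all 10000 random lists of matched expression. Usp17la, a deubiquitinase gene, and Slc47a1, an exporter of organic cations, fell by 4.32 (SE 0.34) and 3.80 (SE 0.24). They were the other 2 of the 5 lowest genes with a symbol above background in ES and iPS cells.

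Of 26 pluripotency genes 2 rose (Dppa3 and Sall4) and 5 fell (Zfp42, Tcl1, Lefty1, Lefty2 and Nr5a2), or 4 and 9 adjusted over the list alone. Zfp42 fell by 3.69 (SE 0.16, 12.9-fold, adjusted p = 0.0425) and Lefty2, an inhibitor of Nodal signalling, by 2.66. The list's median was -0.11, at percentile 10.2 of random lists. The epithelial list had a median of 1.21, above all 10000 random lists: Cldn7, a tight junction gene, rose by 1.89 (SE 0.10, adjusted p = 0.0425), as did Cldn6 and Esrp1, and adjusted over the list alone 9 rose and 2 fell. Krt8 was at 1.99 in ES cells, 4.17 in line 7 and 2.996 in line 13 and did not pass.

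Cdx2, the trophoblast regulator, rose by 2.32 (SE 0.10) and Esx1 rose too, 2 of 5 trophoblast genes (3 adjusted over the list alone). Eomes rose by 2.04 (SE 0.095) and Evx1 rose, 2 of 11 mesoderm genes (6 risen and 2 fallen over the list alone). In the neuroectoderm list Olig2 rose, at least 38.9-fold higher since ES cells had no signal well above background, and Hes5 fell by 3.23 (SE 0.25), as did Otx2 and Neurod1 (3 risen and 5 fallen over the list alone). Of 13 primitive endoderm genes 9 were higher, and Sox7 alone rose past the threshold. The methylation genes Dnmt3b and Dnmt3l rose by 1.57 (SE 0.094) and 1.08 (SE 0.092), 2 of 13 in their list, and Peg3 rose by 2.19 (SE 0.094) with Plagl1 and Peg12, 3 of 21 imprinted genes outside Dlk1-Dio3. Neither Dlk1 nor Dio3 passed over all genes, with differences of 0.31 and -0.36, but over the list alone 1 rose and 1 fell. Rhox5 rose by 2.31 (SE 0.15), 1 of 16 germ cell genes, and Kdm5d rose, 1 of 3 sex-linked genes. Over the list alone, 3 germ cell genes rose and 4 fell, and 3 sex-linked genes rose. There 1 imprinted gene outside Dlk1-Dio3 and 1 methylation gene fell besides those risen. Medians of the trophoblast, mesoderm, primitive endoderm and these imprinted genes were 1.55, 0.43, 0.35 and 0.21. They lay at percentiles 99.97, 99.4, 99.35 and 99.2 of random lists, but the mesoderm median was -0.22 above background on all arrays. Neuroectoderm, methylation and germ cell medians lay at percentiles 65.9, 47.0 and 84.7.

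Among blood lists, Chil3 (-2.21, SE 0.11), Irf8 (-1.17, SE 0.094), Vwf (-1.80, SE 0.10), Cd8b1, Klf1 and Epb42 fell, and genes that rose included Blnk (1.01, SE 0.094); no pan-haematopoietic or progenitor gene passed over all genes. Over the list alone, 1 progenitor gene rose and 2 fell, 5 erythroid genes rose and 3 fell, and 2 B cell genes rose and 1 fell. Blk passed too but was not well above background in ES or iPS cells. No gene passed in the fibroblast, mesenchymal, cell cycle, CDK inhibitor, glycolysis, antigen presentation or immediate early and heat shock lists. Medians of these lists were 0.26, 0.38, -0.23, -0.09, -0.11, 0.25 and 0.41, and lay, in the same order, at percentiles 99.99, 99.46, 0.21, 35.61, 19.7, 99.14 and 100 of random lists. Adjusted over the list alone, 6 immediate early and heat shock genes rose and 3 fell, and 1 antigen presentation gene rose. Among genes with a symbol above background in ES and iPS cells, the 5 highest were Thumpd1 (5.78, SE 0.092), Olig1 (5.58, SE 0.11), the neighbour of Olig2 in gene order, Nlrp4f (3.76, SE 0.15), Serpina3m (3.66, SE 0.21) and Imp4 (3.64, SE 0.13). Thumpd1 was at -2.82 in ES cells, 2.95 and 2.96 in lines 7 and 13, and 2.72 in BMMNCs.

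Genes of chromosome 8 were lower as a group in both iPS lines than in ES cells. The median of 601 such genes above background in ES and iPS cells was -0.40 in line 7 and -0.38 in line 13, while the medians of the other autosomes and X lay between -0.05 and 0.02 for the mean of both lines. Zfp42, Irf8 and Klf1 are on this chromosome, as are 17 list members in all, and 10 of the 14 above background in ES and iPS cells were lower in the iPS lines. With the chromosome's median shift removed, Zfp42 still differed by -3.30, so the shift makes up a small part of its fall. Of 674 genes tested on chromosome 8, 47 were called, 43 of them lower, against 993 called of 21216 tested in all, which include transcripts with no chromosome assigned. Y-linked Ddx3y, Eif2s3y and Kdm5d differed by 0.74, 1.03 and 3.09, the last with no signal well above background in ES cells.

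**Figure D3:**
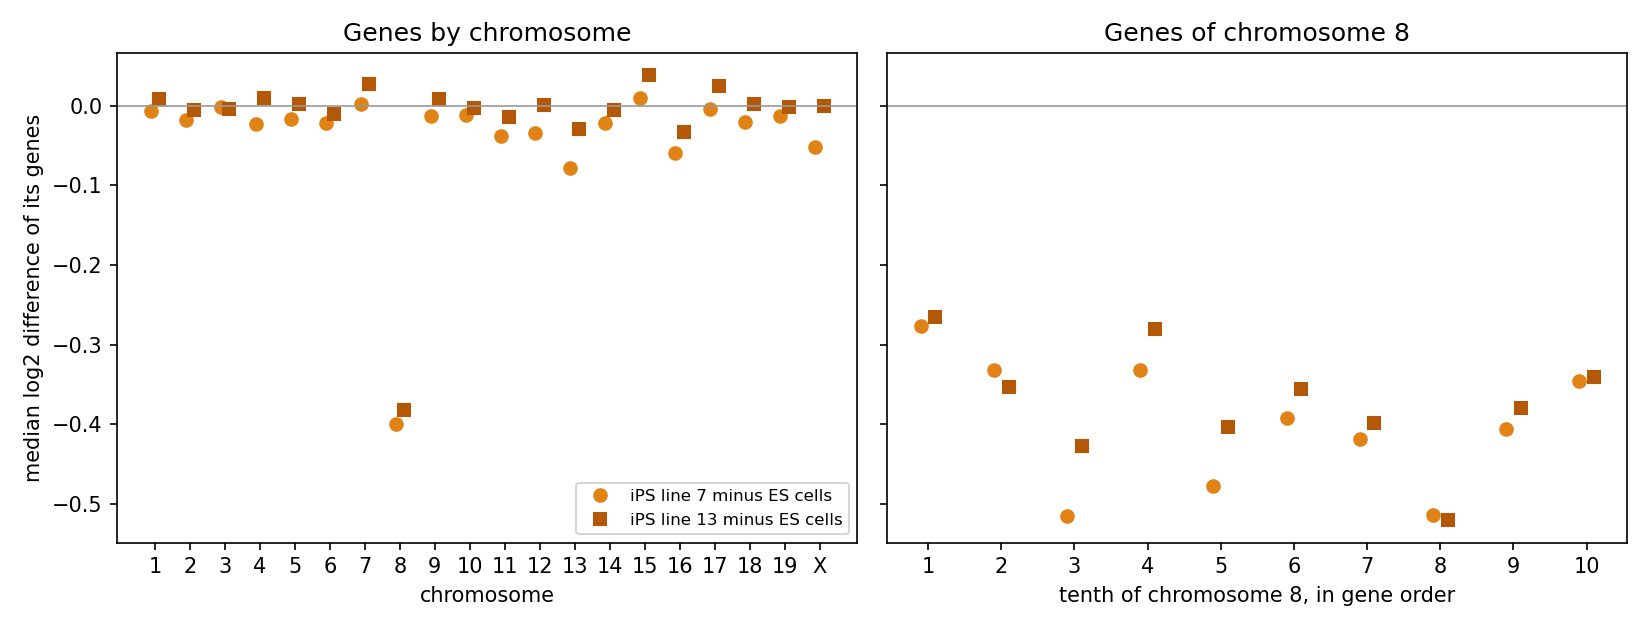
Median log2 difference from ES cells of genes above background in ES and iPS cells (vertical axis), by chromosome (left, X included) and by 10 parts of chromosome 8 in gene order (right), with circles for iPS line 7 and squares for line 13. Chromosome 8 lies at -0.40 and -0.38, and its parts lie between -0.27 and -0.49 for the mean of both lines.

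In all, 412 genes rose and 581 fell, 4.68% of those tested (limma, adjusted p of 0.05), and the smallest adjusted p of any gene was 0.0425. By size, 500 genes were at least 2-fold higher in both lines and 881 at least 2-fold lower, 546 of these 1381 above background on a single side. The rule is uneven, since a higher gene had to be well above background on both iPS arrays and a lower gene on the ES array alone. The split was 770 and 1005 without line 7, 878 and 1100 without line 13, and 225 and 258 above background on all arrays. Both rules, size and adjusted p, were met by 943 genes. The call rests on settings: no gene passed with the authors' value table or without the filter on dim probes (6634 and 4676 at an unadjusted p under 0.05), and 7578 passed with an intensity trend in limma, 5671 with normexp and 5716 among genes above background on every array. Strain, cell origin and reporter also separate the iPS lines from ES cells. Of the 993 called genes, 593 were well above background in ES cells and in at least 1 iPS line. Another 375 were so on a single side, and 25 on neither.

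ES cells were set against BMMNCs as the established pluripotent reference, with 1 array each, and described by size alone, with no test run. At least 4-fold higher were 3673 genes and at least 4-fold lower 3344, of which 4012 were above background on a single side. Here too the balance turned, to 3182 higher and 3845 lower with median scaling, 1736 and 2112 with normexp, and 1357 and 1543 above background on all arrays. Pou5f1 and Sox2 were at least 795.7-fold and at least 569.8-fold higher in ES cells, Klf4 2.14-fold higher and Myc 2.31-fold lower. Of 26 pluripotency genes 23 were at least 4-fold higher: Zfp42 at least 4296-fold, Esrrb at least 491.8-fold and Dppa5a 3646-fold. Among genes with a symbol above background on both arrays, Tdh, Igfbp2, Col18a1 and Col1a1 followed Dppa5a as the highest, with differences of 11.70, 9.81, 9.20 and 9.004.

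Blood genes were lower in ES cells by at least 4-fold in 16 of 17 pan-haematopoietic, 20 of 20 granulocyte, 11 of 12 monocyte and macrophage, 15 of 15 B cell, 12 of 17 T and NK cell, 16 of 16 erythroid, 8 of 10 megakaryocyte and 8 of 12 progenitor genes. Among genes with a symbol above background on both arrays, the lowest were Mpo (-13.03), Hbb-bt (-12.44), Hp (-12.11), Ctsg (-11.50) and Slc4a1 (-11.10). Hba-a1, not well above background in ES cells, was at least 25830-fold lower. Ptprc differed by -8.11, Cybb by -9.02, Dntt by -8.19, Cd34 by -4.14 and Cd74, of class II antigen presentation, by -7.92. At least 4-fold higher were 11 of 12 epithelial genes (Krt8 5.95, Cdh1 4.28), 25 of 27 fibroblast genes (Col1a2 8.998), 16 of 16 germ cell genes (Stra8 6.44) and 4 of 5 2-cell-like genes. Of these last, Zscan4c was at least 734.7-fold higher and Tcstv1 differed by 4.50. Mest, Dnmt3l, Mybl2, Cdkn1a and Slc2a1 were higher by 6.76, 6.38, 2.70, 3.83 and 4.32, while Cdkn2c, Tbx6, Fos and Ddx3y differed by -5.41, -2.38, -4.005 and -2.35.

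Lines 7 and 13 were compared to describe the spread between lines, with no test. The reprogramming factors differed by -0.01 (Pou5f1), -0.11 (Sox2), -0.18 (Klf4) and -0.17 (Myc), line 7 minus line 13. Among list members above background in both lines, Krt8 (1.17), Cd3e (1.25) and Hand1 (1.30), a factor of trophoblast and mesoderm, were at least 2-fold higher in line 7, and Vav1 (-1.08) was lower, although its other probe, above background on every array, gave 0.082. Among genes with a symbol above background in both lines, Cyp2d12 (2.29), Gria1 (2.10), Sh2d1b1 (1.90) and Rassf4 (1.29) were the other highest in line 7. Cacna1a (-1.91), Rasl10b (-1.74), Cckar (-1.66), Cdh24 (-1.52) and Olfr703 (-1.45) were the lowest there. At least 1 other probe each of Cacna1a, Rassf4 and Sh2d1b1, not well above background in either line, gave the opposite sign, and another probe of Rassf4, above background on every array, gave 0.086. In all 280 genes were at least 2-fold higher in line 7 and 237 lower, 466 of these 517 above background in a single line. The balance turned to 99 higher and 189 lower with a floor, 58 and 63 with normexp, and 8 and 22 above background on all arrays. The 27 fibroblast genes had a median of 0.14, with 26 higher in line 7, and the 26 pluripotency genes a median of -0.11. Vav1 turned to 0.052 with normexp, and 30 genes were 2-fold apart among those above background on all arrays.

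Of 158 probes with 10 spots each, all above background, 85 (53.8%) differed between lines by more than 3 standard errors of their spots, an error that holds no variation between arrays. Across genes, Pearson's r was 0.9902 between the lines, 0.974 and 0.977 between ES cells and lines 7 and 13, 0.687 between ES cells and BMMNCs, and 0.684 and 0.690 between lines 7 and 13 and BMMNCs. Over 14859 genes above background on every array these values were 0.998, 0.983, 0.985, 0.762, 0.765 and 0.765. Genes are not independent replicates, so these coefficients describe the arrays and carry no test.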

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

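The settings without chromosome 8, with its shift removed and without fibroblast and macrophage genes were chosen after the result was seen. The count for iPS lines against BMMNCs past limma's adjusted p (16048) stayed within 1.5 times under every alternative run, from 11328 with an added 2-fold rule to 20815 for single probes. That for iPS lines against ES cells (993) did not: it was 0 with the authors' table (6634 at an unadjusted p under 0.05) and 0 with no filter on dim probes (4676), 5671 with normexp, 5716 above background on all 4 arrays and 7578 with an intensity trend. With the authors' table the smallest adjusted p was 0.055, against 0.0425 in the chosen setting. Normexp, which draws dim signals together, and the filter on all arrays, which removes genes seen on a single side, lowered counts by size. These gave 3649 and 2680 for iPS against BMMNCs at 4-fold (6412), 628 and 483 for iPS against ES at 2-fold (1381), 3848 and 2900 for ES against BMMNCs (7017), and 121 and 30 between lines (517), where a floor gave 288. Leaving out either line gave 6873 to 6878 genes for iPS against BMMNCs by size and 1775 to 1978 for iPS against ES, with 22 lists outside the central 95% of random lists in the former either way (22) and 10 to 13 in the latter (12). With the normexp setting, Pearson's r was 0.986 for ES cells and the iPS mean (0.978), 0.755 for BMMNCs and the iPS mean (0.689) and 0.998 between lines (0.9902). Above background on all arrays these were 0.985, 0.765 and 0.998, and quantile normalization gave 0.684 for BMMNCs and the iPS mean.

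Among values past their threshold, those that changed sign were Tcstv1 in iPS against BMMNCs, at 0.021 with the mean of its probes and 0.18 with ES and iPS arrays as 1 group, and Vav1 between lines, at 0.052 with normexp. Above background on all arrays the median of the reprogramming factors against BMMNCs became -0.070, since Pou5f1 and Sox2 drop out there, and that of the mesoderm list against ES cells -0.22, over fewer genes. Among named genes in iPS against ES cells, 216 of the values under alternatives kept their call, 53 lost it and 1, Sox2 with an intensity trend, gained it, and no value past the threshold changed direction. Among values not past it, the small differences of Pou5f1, Klf4 and Myc from ES cells changed sign with the scaling, reaching 0.061, 0.069 and 0.062 with median scaling, as did Pou5f1 between lines (0.047 with quantile normalization). In iPS against BMMNCs 846 kept it, 13 lost it (Eomes, Elf5, Ascl2, Pax6 and Tcstv1 in 2 settings each, Zscan4c, Fosb and Hk1 in 1) and 4 gained it (Sox1 in 3, Gata4 in 1), besides the 2 reversed Tcstv1 values. Without chromosome 8, and with its shift removed, 854 and 945 genes passed in iPS against ES cells; without fibroblast and macrophage genes 16005 passed against BMMNCs. Median scaling moved the median of all genes for iPS against BMMNCs to -0.25, against -0.04 in the chosen setting, so small differences there depend on scaling. Without either line no residual degree of freedom is left, so named genes were not tested there. Other causes were not tested. No paired analysis was possible because the groups share no replicate numbers in the labels, and the planned slide block was not run on a single slide. Signal over background limits dim genes, whose folds are bounds.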

Other observations

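The tests of expression level, of fibroblast and macrophage genes and of strain in this part were chosen after the result was seen; the tests of the share, the parts along the chromosome and the BMMNC contrast of chromosome 8 were written once its median was known but before their own values. The large difference of Olig1 and Olig2 from ES cells was not shared by the next genes in gene order, Ifnar2 and Il10rb. These differed by 0.14 and 0.32, against 5.58 for Olig1, and were already at 0.57 and 0.44 in ES cells. On the other side, 4932438H23Rik was above background in line 13 alone, at -3.50 against -7.48 in line 7 and -7.24 in ES cells. Granulocyte genes were well above background in 5, 4 and 5 of 20 cases in ES cells, line 7 and line 13, and in 20 of 20 in BMMNCs, while monocyte and macrophage genes were above it in 10 of 12 cases on each ES and iPS array. The macrophage list was not alone in this. In ES cells 10 of 12 progenitor, 12 of 17 pan-haematopoietic and 9 of 15 B cell genes were above background, with the same counts on both iPS arrays. For T and NK cell, erythroid and megakaryocyte genes the counts in ES cells were 8 of 17, 10 of 16 and 5 of 10.

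The 601 chromosome 8 genes had a median iPS minus ES difference of -0.39, a 1.31-fold higher level in ES cells. Normalization or expression level is argued against, since the lowest of 10000 matched random lists reached -0.07 and the chromosome stayed between -0.39 and -0.35 relative to the other autosomes under quantile normalization and normexp. The share of its genes below the median of the other autosomes was 81.5%. This share follows in large part from the chromosome's median, known when the rule was written, so it is not separate evidence. Differences of single genes by strain or probe are argued against by 10 parts of the chromosome in gene order, the highest of which had a median of -0.27. A change along the whole chromosome may therefore be the source. Relative to other genes, chromosome 8 differed from BMMNCs by 0.059 in the iPS lines (95% bootstrap interval -0.08 to 0.21) and by 0.39 in ES cells (0.23 to 0.56). The values lie nearer to a gain in ES cells than to a loss in the iPS lines. The intervals resample genes and hold no variation between arrays. How far other chromosomes differ between these cell types and BMMNCs was not measured, so a loss is not excluded. An extra copy of chromosome 8 in all or a part of the ES cells is a candidate explanation, and it was not tested on DNA. A ratio of 3 copies over 2 in every cell would give 0.585 if signal followed copy number exactly. That was not checked, so the lower value does not show that only a part of the cells carry it.

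Fibroblast genes stood high in ES cells and both iPS lines, with Col1a2 at 7.30, 7.60 and 7.52, although feeders had been depleted on gelatin. All 27 were above background on each of these arrays and none belongs to another list. Of these 27 genes, 26 were higher in line 7 than in line 13, with a median difference of 0.14. The SD of the differences, 0.074, lay at or above that of only 0.57% of matched random lists. Those lists were matched on mean expression with BMMNCs included, where fibroblast genes were far lower. Matched genes may thus be dimmer on the iPS arrays and spread more, so the SD cannot decide whether the differences moved together. RNA of feeder or fibroblast-like cells in a share that differs between arrays may explain the shared direction. Expression by the stem cells themselves was not tested and stays open. Marrow cells left in the iPS cultures are argued against for the macrophage genes, whose 10 members above background in ES and iPS cells had a median iPS minus ES difference of 0.026 (95% bootstrap interval -0.12 to 0.11), ES cells holding no marrow. The interval resamples these genes and holds no variation between arrays, and ES cells were read on a single array.

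In both lines at least 4-fold apart from ES cells were 460 genes, and 85 of them were above background on all 4 arrays. If strain, which the iPS lines and BMMNCs share, were the source, BMMNCs would lie near the iPS level. They lay within 2-fold of it for 34 of the 85 genes, or 40.0%, and within 2-fold of the ES level for 10. Random lists matched on the iPS level gave a median of 56.5% and a 95th percentile of 64.7%, so the 40.0% met the first rule of the test, which argued against strain; the rule was then replaced and the verdict opened, because these lists were drawn from genes that differ little between iPS and ES cells, which may also differ less between cell types. Strain cannot be told apart from cell origin for these genes, Thumpd1 among them with BMMNCs 0.24 below the iPS mean, because both set the iPS lines apart from ES cells, and no biological explanation was tested.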
